A study of Homo sapiens with 798 samples.

How the data were processed

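Expression was measured on 798 Affymetrix human high-throughput arrays hybridised with labelled RNA from 756 established human tumour cell lines. Per the file headers, the deposited per-array tables hold a signal (a linear intensity), a detection call and a detection p-value for each of 22277 probe sets. The deposited signals were not on 1 scale between arrays, with array means from 29.1 to 822, and the version and scaling of the export are not stated. In all 798 arrays the deposited series value table equalled the per-array signal (largest difference 0), so it was not used. The labels gave tissue, histology, plate, batch and a line number. Each cell line was taken as 1 independent sample, and lines that may share a donor were not looked for. The 2 arrays of 42 lines were technical repeats of a line, averaged before any test. Scanner settings were not used. The 62 control probe sets, the 1923 with no symbol, the 568 with several symbols and 31 for genes tied to sex chromosomes were left out. No 2 arrays were identical in their values.

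Signals were quantile normalised over the 798 arrays and taken as log2(signal + 16), a scale on which the change of dim genes is understated. Of the probe sets with exactly 1 symbol, the one with the highest mean was kept for each of 12143 genes. A gene was tested where it was called present (detection p under 0.05) on at least 0.5 times as many lines as the smaller group held. For a gene called present on no line of a side the fold is a lower bound, taken against the higher of each array's lowest signal with a present call and the probe set's own signal. Arrays had 32.2% to 61.4% of probe sets present, and the SD of 1 array, from repeats of a line, had a median of 0.31 in log2.

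Lines were grouped by tissue and histology as labelled, and groups of at least 6 lines served as reference groups for solid tumours. The comparisons of groups used linear models with moderated tests in limma 3.58.1 (R 4.3.3), with Benjamini-Hochberg adjustment over the genes tested. A gene passed at an adjusted p under 0.05 and a log2 difference of at least 1 in size. A solid group was set against the unweighted mean of 28 other solid groups. Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 115 list tests, 39 calls were lost with the estimated correlation, and each is given with its p. The other passing lists kept their call there at an adjusted p of up to 0.0362, often far above the first p. For these the second p is given in part only, so the first p overstates the strength of the rest too. Lists, comparisons, their main tests and the rule for named genes were fixed before the data were examined. The rule named the 10 genes with the largest differences each way in comparisons of 2 groups, the 10 highest and the 4 lowest for a solid group against the others, and the 4 members of each list with the largest differences, passing or not; the text names a part of these. Listed genes with no probe set of their own symbol, such as ASCL1 and TP63, are not analysed here. Members called present on too few lines were left out as well, so counts of a list cover only the members tested. In myeloid against lymphoblastic leukaemia 13 of 25 listed myeloid genes were tested. In lung squamous against adenocarcinoma lines 14 of 26 listed squamous genes were. Within plates, a list's difference was computed where both sides had at least 2 lines.

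The fit was checked on simulated data, in which true log2 changes of 1.5 were recovered for 72% to 100.0% of genes and changes of 2 for 88% to 100.0% over 6 comparisons, with 0 to 7 unchanged genes called. The simulated values were independent normal draws with 1 spread per gene. They held no correlation between genes, no unequal spread of groups and no plate effect, so these rates need not hold for the real lines. Alternatives were each array scaled to 1 median, offsets of 1 and 64, no detection filter or one at 25% of the lines, the mean of a gene's probe sets, every probe set, plate as a block, batch 1 alone, the first array of a repeated line, and other reference groups. Added after the data were seen were batch 2 alone, supplier as a block for the squamous lines of oesophagus and head and neck, the ACTB 3' to 5' ratio as a covariate, and the removal of 258 arrays with under 40% of probe sets present or an ACTB log2 ratio over 4. Other splits of the lines (100 per comparison) and permutation tests (100000 resamples) used fixed seeds. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Sex, age and origin of donors were not analysed.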

Results

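Messenger RNA was measured in established human tumour cell lines on an Affymetrix high-throughput array that held 22277 probe sets. The 798 arrays covered 756 cell lines, of which 42 were on 2 arrays, and the labels placed the lines in 52 groups by tissue of origin and histology. Lung small cell carcinoma (54 lines), glioma (51), breast (42), melanoma (41), colorectal (39), neuroblastoma (39) and lung adenocarcinoma (36) were among the groups compared, and 1 array whose labels gave no tissue entered no comparison. Labelled RNA had been prepared on 9 plates, and the arrays had been run in batch 1 (630 arrays) and batch 2 (168 arrays). The mean signal of an array ranged from 29.1 to 822 with a median of 322, and between 32.2% and 61.4% of probe sets were called present with a median of 51.6%. The log2 ratio of the 3' to the 5' probe set of ACTB, a measure of RNA degradation, ranged from 0.31 to 6.19. It averaged 4.08, 4.68 and 5.09 on plates 3, 4 and 5, and 1.5 to 2.2 on the others. Fits with this ratio and the removal of arrays of high ratio are therefore in large part tied to plate. The number of arrays limits the precision of every value. Each difference below is a log2 difference ± its standard error, and a gene passed at a limma adjusted p under 0.05 and a difference of at least 1 in size. The standard error rests on the spread of cell lines pooled over all groups of a fit. For a group whose lines vary more than the others it is too small. Counts of passing list members were the same when adjusted over the list alone, except where a second count is given.

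The lines hybridised in both batches asked how far the same line differed between batches. Across 31 such lines and 8267 genes the median difference of batch 2 from batch 1 was 0.010 (SD over genes 0.14), and 0 genes passed in limma. The unadjusted p was under 0.05 for 2444 genes, and 1304 genes had an adjusted p under 0.05 at differences smaller than 1. The standard deviation of 1 array over genes had a median of 0.31 for the 31 pairs across batches and 0.32 for the 11 pairs within batch 2, and the medians did not differ beyond chance (two-sided permutation p = 0.540). Over all 42 pairs it ranged from 0.25 to 0.58, and Pearson r across genes, which are not independent replicates, had a median of 0.974.

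Which genes separate tumour lines of blood cells from lines of solid tumours was asked with 127 haematological and 628 solid lines. All 30 leukocyte genes were higher in haematological lines, with a mean difference of 3.62 (camera adjusted p = 1.83e-71). LAPTM5 (6.13 ± 0.15), a lysosomal protein of blood cells, PTPRC (4.92 ± 0.11), which encodes the leukocyte common antigen CD45, and the actin regulator CORO1A (5.01 ± 0.11) were among them. PTPRC was called present on 86.6% of haematological and 2.1% of solid lines. The small actin-binding protein GMFG (5.19 ± 0.10), the tetraspanin CD53 (4.84 ± 0.08), the guanine exchange factor DOCK2 (4.63 ± 0.08) and the chemokine receptor CXCR4 (4.60 ± 0.21) also stood among the 10 genes with the largest rise. All 10 MHC class II genes, which present antigen to T cells, were higher (camera adjusted p = 1.18e-10, adjusted p = 0.0199 with an estimated correlation), with HLA-DRA (3.83 ± 0.20) and its chaperone CD74 (3.71 ± 0.19) as examples. PECAM1 (2.01 ± 0.11), an adhesion molecule of platelets, leukocytes and endothelium, was higher, while the endothelial receptor KDR (-0.04 ± 0.07) did not pass, and too few endothelial genes were measurable for a list test. Adhesion and caveolae genes fell in 22 of 23 members (camera adjusted p = 1.07e-19, adjusted p = 0.00373 with an estimated correlation), with the growth factor receptor EGFR (-3.60 ± 0.21) and the laminin chain LAMB1 (-3.92 ± 0.16). Among 23 epithelial genes 21 were lower (camera adjusted p = 1.64e-08, adjusted p = 0.178 with an estimated correlation), with KRT18 (-4.63 ± 0.25), a keratin of simple epithelia, and the desmosomal DSP (-3.62 ± 0.25). Of 22 mesenchymal genes 11 fell and 3 rose (camera adjusted p = 0.0204, adjusted p = 0.434 with an estimated correlation), with FN1 (-4.01 ± 0.29), which encodes fibronectin, furthest down. Of 25 cell cycle genes 6 were higher and none lower (camera adjusted p = 2.19e-05, adjusted p = 0.312 with an estimated correlation), among them the replication helicase subunit MCM5 (1.37 ± 0.10). Of 20 interferon response genes 5 were higher and 1 lower, and the list did not pass (camera adjusted p = 0.221). In total 1365 of 9692 genes passed, 451 higher and 914 lower, and 794 passed with an offset of 64 before the logarithm. The leukocyte difference was 2.92 to 4.06 within the 9 plates, and the adhesion difference -2.86 to -1.27. The arrays of haematological lines had 48.0% of probe sets present against 52.0% in solid lines.

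How small cell lung carcinoma differs from other lung carcinoma was asked with 54 small cell and 72 non-small cell lines. All 20 neuroendocrine genes were higher in small cell lines (camera adjusted p = 1.21e-17, adjusted p = 0.00228 with an estimated correlation), with a mean difference of 3.36. INSM1 (6.42 ± 0.32), a transcription factor of neuroendocrine cells, CHGA (4.42 ± 0.31), a protein of secretory granules, and the neural adhesion molecule NCAM1 (4.76 ± 0.32) were among them. INSM1 was called present on 96.3% of small cell and 9.7% of other lines. BEX1 (6.23 ± 0.37), the tubulin gene TUBB2B (4.52 ± 0.33) and the axonal motor protein KIF1A (4.31 ± 0.27) rose as well. Of 14 sympathetic neuron genes 11 were higher and 1 lower (camera adjusted p = 1.19e-06), with the RNA-binding protein ELAVL4 (3.66 ± 0.28). The sympathetic neuron list shares genes with the neuroendocrine list, ELAVL4 among them, so the lists are not independent. Cell cycle genes were higher in 14 of 25 (camera adjusted p = 1.72e-08, adjusted p = 0.194 with an estimated correlation), with the helicase subunit MCM2 (1.58 ± 0.18) and the thymidylate synthase TYMS (1.49 ± 0.21). Of 23 adhesion and caveolae genes 22 were lower (camera adjusted p = 1.69e-18, adjusted p = 0.00228 with an estimated correlation), with CAV1 (-4.37 ± 0.34) and CAV2 (-4.61 ± 0.29), the caveolins, and the coactivator of the Hippo pathway WWTR1 (-3.75 ± 0.29). The membrane repair protein MYOF (-5.19 ± 0.29), the calcium-binding S100A10 (-4.90 ± 0.35) and ANXA1 (-4.75 ± 0.36), an annexin, were also among the 10 largest falls. Of 18 interferon response genes 14 fell (camera adjusted p = 7.12e-07, adjusted p = 0.156 with an estimated correlation), with ISG15 (-2.58 ± 0.33) and IFITM1 (-3.00 ± 0.32), both induced by interferon. Of 6 MHC class II genes 4 fell (camera adjusted p = 0.0419, adjusted p = 0.400 with an estimated correlation). Epithelial genes fell in 9 of 23 and rose in 2 (camera adjusted p = 0.0357, adjusted p = 0.579 with an estimated correlation), with KRT7 (-3.28 ± 0.40) lower. Lists that did not pass were the mesenchymal one (6 of 19 lower and 2 higher, camera adjusted p = 0.113), where VIM (-2.89 ± 0.51) fell and CDH2 (2.91 ± 0.40) rose, and the squamous one (4 of 9 lower, camera adjusted p = 0.113). Neither did lung epithelium and mucin genes (3 of 9 higher and 2 lower, camera adjusted p = 0.481), where NKX2-1 (1.81 ± 0.32), a lung transcription factor, rose and the mucin regulator AGR2 (-2.47 ± 0.55) fell, nor leukocyte genes (1 of 9 higher and 2 lower, camera adjusted p = 0.481). In total 1505 of 8586 genes passed, 696 higher and 809 lower. The count was 874 with an offset of 64 and 830 in batch 2 alone, where CEACAM6 and the median of the epithelial list turned from lower to higher. The MHC class II list, with a median of -1.15, lost its call there at a median of -0.44 (adjusted p = 0.190), with each array scaled to 1 median at -1.09 (0.106), with an offset of 64 at -0.76 (0.0530) and with a filter at 25% of the lines at -1.12 (0.0702). The epithelial list, with a median of -0.52, lost its call with the median scaling at -0.60 (0.0881) and an offset of 1 at -0.49 (0.0512), its size little changed. The arrays of small cell lines had 50.5% of probe sets present against 52.6%. The neuroendocrine difference was 2.53 to 3.90 within 7 plates and the epithelial one -2.08 to 1.53.

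Whether lung squamous and adenocarcinoma lines keep the expression of their histologies was asked with 11 and 36 lines. Of 9122 genes 2 passed: the adaptor EFS (1.80 ± 0.33), which binds Src family kinases, was higher in squamous lines (adjusted p = 0.0165), and the RNA-binding protein RBM47 (-2.48 ± 0.49) was lower (adjusted p = 0.0275). None of the 14 squamous genes passed over all genes and 2 did adjusted over the list alone (3 at an unadjusted p under 0.05, camera adjusted p = 0.0452, adjusted p = 0.660 with an estimated correlation). The largest squamous differences were those of the calcium-binding protein S100A2 (2.15 ± 0.69) and the desmosomal plakophilin PKP1 (1.34 ± 0.42). Of 11 lung epithelium and mucin genes none passed, and 2 were lower adjusted over the list alone (4 at an unadjusted p under 0.05, camera adjusted p = 0.0104, adjusted p = 0.517 with an estimated correlation), with differences for the membrane mucin MUC1 (-2.66 ± 0.60) and the adhesion protein CEACAM6 (-3.04 ± 0.89). Of 23 epithelial genes none passed, and 2 were lower adjusted over the list alone (3 at an unadjusted p under 0.05, camera adjusted p = 0.0104, adjusted p = 0.660 with an estimated correlation), where the keratins KRT8 (-1.59 ± 0.45) and KRT18 (-1.15 ± 0.34) had values below those of adenocarcinoma. None of 25 cell cycle genes passed (0 at an unadjusted p under 0.05, camera adjusted p = 0.0141, adjusted p = 0.660 with an estimated correlation). The 21 mesenchymal genes (4 at an unadjusted p under 0.05, camera adjusted p = 0.325) held 1 higher gene adjusted over the list alone, and their median of -0.01 and mean of 0.21 differed in sign. None of 12 neuroendocrine genes passed (1 at an unadjusted p under 0.05, camera adjusted p = 0.216), none of 17 hypoxia genes (3 at an unadjusted p under 0.05, camera adjusted p = 0.522, 1 lower adjusted over the list alone, median 0.03 and mean -0.11), and none of 13 leukocyte genes (1 at an unadjusted p under 0.05, camera adjusted p = 0.949, median -0.01 and mean 0.05). The mean signal of the arrays was 267 in squamous and 329 in adenocarcinoma lines. A single plate held at least 2 lines of each kind, and its squamous difference was 0.80 to 0.80. Neither gene passed with plate as a block (1.27 for EFS and -2.66 for RBM47), where 1 other gene did, and 17 genes passed without arrays of low quality. All 4 passing lists lost their call with plate as a block (adjusted p from 0.346 to 0.891) and in batch 1 alone (0.0522 to 0.409). The squamous median of 0.27 was 0.17 with plate and 0.25 in batch 1, the mucin median of -0.68 was -0.28 and -0.20, and the cell cycle median of 0.24 was 0.12 and 0.30. The epithelial median of -0.52 was -0.087 with plate, -0.0001 in batch 1 (adjusted p = 0.409) and -0.13 without arrays of low quality (adjusted p = 0.110). The squamous list also lost its call with an offset of 1 at 0.39 (0.0851) and a filter at 25% of the lines at 0.27 (0.0541).

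How squamous carcinoma lines of the oesophagus differ from those of the head and neck was asked with 22 lines of each. Interferon response genes were lower in oesophageal lines, 10 of 20 over all genes and 17 adjusted over the list alone (camera adjusted p = 4.33e-22, adjusted p = 0.0362 with an estimated correlation), by a mean of 1.69. IFIT2 (-2.33 ± 0.36), MX1 (-2.50 ± 0.56) and IFI27 (-3.26 ± 0.76), all induced by interferon, were among those that fell, and the interferon-induced TRIM22 (-3.07 ± 0.54) fell outside the list. IL1B (-2.86 ± 0.47), which encodes interleukin 1 beta, the chemokine CCL20 (-2.80 ± 0.42) and the acute phase protein SAA1 (-3.52 ± 0.52) were lower too. INHBA (-3.72 ± 0.46), which encodes a subunit of activin, had the largest fall, and was present on 36.4% of oesophageal and 90.9% of head and neck lines. The calcium-binding proteins S100A8 (-3.25 ± 0.81) and S100A9 (-2.98 ± 0.68) fell as well. Of 15 mesenchymal genes 2 were lower, FN1 (-2.70 ± 0.75) and SPARC (-2.87 ± 0.70) (camera adjusted p = 0.00257, adjusted p = 0.294 with an estimated correlation). Higher genes included the glutathione transferase GSTM3 (2.35 ± 0.59), PLAC8 (2.10 ± 0.47) and the tight junction protein CLDN4 (1.64 ± 0.45), the 1 epithelial gene of 23 to pass, with 2 adjusted over the list alone (camera adjusted p = 0.220). None of 21 squamous genes passed (8 at an unadjusted p under 0.05, camera adjusted p = 0.00180, adjusted p = 0.382 with an estimated correlation), with values for the basal keratin KRT14 (-2.91 ± 0.94) and the suprabasal keratin KRT13 (1.95 ± 0.88) that pointed opposite ways. None of 3 gastric genes passed (2 at an unadjusted p under 0.05, camera adjusted p = 0.184), none of 3 intestinal genes (1 at an unadjusted p under 0.05, camera adjusted p = 0.704, 1 lower adjusted over the list alone, median 0.29 and mean -0.19), none of 16 hypoxia genes (3 at an unadjusted p under 0.05, camera adjusted p = 0.0373, adjusted p = 0.294 with an estimated correlation), and none of 25 cell cycle genes, where 1 was higher adjusted over the list alone (3 at an unadjusted p under 0.05, camera adjusted p = 0.0454, adjusted p = 0.703 with an estimated correlation). In total 103 of 8180 genes passed, 20 higher and 83 lower. With plate as a block 10 passed, 9 of them among the 103, and with supplier as a block 35 passed, 23 of them among the 103. Batch 1 alone gave 63 and batch 2 alone 4, where FN1 turned to 0.064 and the hypoxia median went from -0.33 to -0.036, its call lost (adjusted p = 0.543). The cell cycle median of 0.17 turned to -0.18 in batch 2 alone and to -0.040 with plate as a block. That list lost its call with supplier as a block at 0.039 (adjusted p = 0.347), the median scaling at 0.084 (0.0745), the ACTB covariate at 0.17 (0.0585), an offset of 64 at 0.16 (0.0637) and the mean of probe sets at 0.17 (0.0681). The squamous list, with a median of -0.44, lost its call with plate at -0.26 (adjusted p = 0.222) and supplier at -0.42 (0.0555) as a block. Within 3 plates the interferon difference was -3.12 to -0.01, and with plate as a block the estimated correlation gave adjusted p = 0.146 for that list.

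What separates colorectal from stomach lines was asked with 39 and 25 lines. Of 17 intestinal genes 10 were higher in colorectal lines, 13 adjusted over the list alone, and none was lower (camera adjusted p = 3.17e-14, adjusted p = 0.0178 with an estimated correlation). CDH17 (3.40 ± 0.76), a cadherin of the intestine, the tetraspanin TSPAN8 (3.25 ± 0.82), KRT20 (2.97 ± 0.66), a keratin of intestinal epithelium, and the galectin LGALS4 (2.83 ± 0.75) led the list. KRT20 was called present on 76.9% of colorectal and 16.0% of stomach lines. RNF43 (2.33 ± 0.44), a ubiquitin ligase that restrains Wnt receptors, and the ferroxidase HEPH (2.47 ± 0.59) were also higher. Of 5 gastric genes 1 was lower, GATA4 (-1.64 ± 0.26), a transcription factor of the stomach, and the list did not pass (camera adjusted p = 0.0528). Of 23 epithelial genes 4 were higher, or 15 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.95e-09, adjusted p = 0.214 with an estimated correlation), with CDH1 (2.12 ± 0.64), which encodes E-cadherin. The inducible heat shock protein HSPA1A (-3.41 ± 0.67) had the largest fall, and UCHL1 (-2.06 ± 0.62), LGALS1 (-2.08 ± 0.62) and the actin-binding CALD1 (-1.85 ± 0.54) were lower. None of 11 mesenchymal genes passed while the list did (6 at an unadjusted p under 0.05, camera adjusted p = 1.10e-04), with a value for VIM (-1.29 ± 0.62) of the same sign. Of 19 interferon response genes 1 was lower, BST2 (-1.81 ± 0.50) (camera adjusted p = 0.0276, adjusted p = 0.613 with an estimated correlation). None of 25 cell cycle genes (2 at an unadjusted p under 0.05, camera adjusted p = 0.300) and none of 9 leukocyte genes passed (2 at an unadjusted p under 0.05, camera adjusted p = 0.721). In total 172 of 8356 genes passed, 129 higher and 43 lower. The count was 91 with an offset of 64, 105 in batch 1 alone and 15 in batch 2 alone, where HSPA1A and the median of the interferon list were higher in colorectal lines. With plate as a block LGALS4, CDH1 and CALD1 missed the threshold at values of 2.69, 1.99 and -1.76, and UCHL1 at adjusted p = 0.0544. The intestinal difference was 1.26 to 2.90 within 6 plates. The epithelial and interferon differences changed sign between plates, from -1.38 to 2.31 and from -3.08 to 1.21.

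How lines labelled as myeloid leukaemia differ from lymphoblastic ones was asked with 28 myeloid and 32 acute lymphoblastic leukaemia lines. The myeloid group included lines labelled as blast phase chronic myeloid leukaemia, a label that does not give the lineage of the blasts. Of 13 myeloid genes 11 were higher and none lower (camera adjusted p = 8.24e-14), among them the signalling adaptor TYROBP (3.18 ± 0.47), the transcription factor CEBPD (2.77 ± 0.44) and the protease inhibitor CST3 (2.70 ± 0.36). MS4A3 (3.67 ± 0.63), a membrane protein of granulocyte precursors, was at least 9.78-fold higher, being called present on no lymphoblastic line. The cyclin CCND2 (3.43 ± 0.55), the membrane protein STOM (3.31 ± 0.43) and the carbonic anhydrase CA2 (2.94 ± 0.53) were also higher. T cell genes fell in 11 of 13, 12 adjusted over the list alone (camera adjusted p = 1.04e-08, adjusted p = 0.157 with an estimated correlation), with the kinases LCK (-4.05 ± 0.58) and ZAP70 (-2.93 ± 0.40) and the transcription factor BCL11B (-2.70 ± 0.55). B cell genes fell in 6 of 14, 8 adjusted over the list alone (camera adjusted p = 0.00187, adjusted p = 0.384 with an estimated correlation), with the surrogate light chain gene IGLL1 (-2.53 ± 0.73) and the coactivator POU2AF1 (-2.56 ± 0.75). LEF1 (-4.17 ± 0.60), a Wnt pathway transcription factor, had the largest fall, and DNTT (-3.04 ± 0.66), the terminal transferase of lymphoid precursors, and RASGRP1 (-3.17 ± 0.54) were lower. Of 4 erythroid and megakaryocytic genes 1 was higher, NFE2 (1.81 ± 0.48) (camera adjusted p = 0.374). None of 25 cell cycle genes passed (13 at an unadjusted p under 0.05, camera adjusted p = 1.49e-04, adjusted p = 0.384 with an estimated correlation), where TOP2A (-0.68 ± 0.18) had a value below that of lymphoblastic lines. Of 16 interferon response genes 1 was higher, BST2 (1.04 ± 0.36) (camera adjusted p = 0.0261, adjusted p = 0.514 with an estimated correlation), and none of 10 MHC class II genes passed (0 at an unadjusted p under 0.05, camera adjusted p = 0.715). In total 524 of 7680 genes passed, 308 higher and 216 lower. The count was 279 with an offset of 64 and 152 in batch 2 alone, where the B cell, cell cycle and interferon lists lost their calls (adjusted p = 0.893 for each) as their medians went from -1.32, -0.43 and 0.56 to -0.36, -0.15 and 0.044. The lymphoblastic lines mixed T, B and unstated lineages, and without the unstated ones IGLL1, VPREB1 and BST2 missed the threshold (adjusted p = 0.0790, 0.153 and 0.127) and the interferon list lost its call at a median of 0.47 (adjusted p = 0.0817), as it did without arrays of low quality at a larger median of 0.60 (0.0807). The myeloid difference was 0.46 to 3.02 within 4 plates and the T cell one -3.33 to 0.03. The B cell difference was -2.73 to 0.11 there and the interferon one -0.28 to 0.86.

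T and B lineage acute lymphoblastic leukaemia were compared in 11 and 9 lines. Of 16 T cell genes 15 were higher in T lineage lines, and all 16 adjusted over the list alone (camera adjusted p = 4.94e-33). CD3D (6.74 ± 0.68), CD3G (5.59 ± 0.64) and CD3E (5.36 ± 0.51), which encode chains of the T cell receptor complex, were called present on no B lineage line, so that their folds are lower bounds: at least 95.9-fold, 33.3-fold and 33.8-fold higher. The signalling adaptor SH2D1A (5.06 ± 0.33) was at least 25.1-fold higher. Transcription factors of the T lineage, GATA3 (4.86 ± 0.49) and BCL11B (4.88 ± 0.48), and the adaptor LAT (4.49 ± 0.38) rose as well. Of 14 B cell genes 11 were lower (camera adjusted p = 1.16e-21), with BLNK (-5.92 ± 0.41), an adaptor of the B cell receptor, and POU2AF1 (-5.21 ± 0.61), a B cell coactivator. The oncogene TCL1A (-7.32 ± 0.57), called present on no T lineage line, was at least 97.3-fold lower, and VPREB3 (-4.60 ± 0.57) at least 18.1-fold lower. The immunoglobulin heavy chain gene IGHM (-5.57 ± 0.52) fell by 5.57 on the log2 scale. Of 10 MHC class II genes 9 were lower, all 10 adjusted over the list alone (camera adjusted p = 2.58e-19), with HLA-DPA1 (-7.09 ± 0.78), HLA-DRA (-6.48 ± 0.76) and CD74 (-5.90 ± 0.82). None of 3 myeloid genes passed (1 at an unadjusted p under 0.05, camera adjusted p = 0.738), and none of 25 cell cycle genes (1 at an unadjusted p under 0.05, camera adjusted p = 0.0248, adjusted p = 0.625 with an estimated correlation). On the cell cycle list 1 of the 9 B lineage lines stood apart below the others, by 0.565 of the range. The erythroid list had too few measurable genes for a test, with values for HBZ (0.10 ± 0.43) and HBE1 (-0.08 ± 0.52). In total 377 of 7474 genes passed, 171 higher and 206 lower. With plate as a block 235 passed, 201 of them among the 377, and without arrays of low quality 69 passed. The cell cycle list, with a median of 0.31, lost its call in both settings at 0.046 and 0.12 (adjusted p = 0.990 and 0.612) and with each array scaled to 1 median at 0.15 (0.0874). Both plates with lines of each kind gave T cell differences from 3.32 to 4.21 and B cell differences from -3.26 to -3.02. The MHC class II difference varied more between these plates, from -5.47 to -1.35.

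How plasma cell myeloma differs from other mature B-cell neoplasms was asked with 12 and 35 lines. The 35 lines were on 16 arrays of Burkitt lymphoma and 21 arrays of other mature B-cell neoplasms. Of 25 genes of the secretory pathway in the endoplasmic reticulum 8 were higher in myeloma and none lower (camera adjusted p = 1.55e-15). SEL1L (1.62 ± 0.30), part of the machinery that retrieves misfolded proteins, the translocon-associated SSR3 (1.44 ± 0.27) and the chaperone HSP90B1 (1.16 ± 0.22) were among them. Of 13 plasma cell genes 5 were higher and 1 lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00107, adjusted p = 0.153 with an estimated correlation). IRF4 (2.52 ± 0.65), a transcription factor of plasma cells, and TNFRSF17 (2.44 ± 0.63), the B cell maturation antigen, rose, and SEL1L3 (-2.36 ± 0.74) fell. MAGEA6 (3.34 ± 0.63), MAGEA3 (3.32 ± 0.72) and CTAG2 (3.10 ± 0.56), each a cancer testis antigen, were among the 10 largest rises. ITM2C (3.56 ± 0.54) had the largest rise, and the inhibitor of apoptosis BCL2 (3.26 ± 0.64) and the costimulatory receptor CD28 (2.64 ± 0.39), 1 of 8 T cell genes to rise beside 1 that fell (camera adjusted p = 0.930), were also higher. Of 16 B cell genes 8 were lower, 9 adjusted over the list alone (camera adjusted p = 3.01e-05, adjusted p = 0.225 with an estimated correlation), with TCL1A (-4.24 ± 0.93), the surface antigen MS4A1 (-2.71 ± 0.80) and the receptor component CD79A (-2.69 ± 0.70). PTPRC (-4.03 ± 0.64), which encodes CD45, the germinal centre repressor BCL6 (-3.77 ± 0.76) and CD27 (-2.96 ± 0.73) fell as well. None of 10 MHC class II genes passed, and 4 were lower adjusted over the list alone (5 at an unadjusted p under 0.05, camera adjusted p = 0.00161, adjusted p = 0.386 with an estimated correlation), with a value for HLA-DPA1 (-2.33 ± 0.94) below that of the other lines. Of 7 myeloid genes 1 was higher, CST3 (2.04 ± 0.61) (camera adjusted p = 0.930, median -0.00 and mean 0.20), and none of 25 cell cycle genes passed (3 at an unadjusted p under 0.05, camera adjusted p = 0.930, median -0.05 and mean 0.01). The ACTB ratio of RNA degradation was 2.16 ± 1.17 (SD) in myeloma and 3.36 ± 1.72 in the other lines, with 49.8% and 46.3% of probe sets present. In total 455 of 8413 genes passed, 252 higher and 203 lower, and 280 did with an offset of 64. With the ACTB ratio as a covariate 224 passed, with plate as a block 171, without arrays of low quality 96, and in batch 2 alone 4, while 723 probe sets passed when each was counted. The median of the cell cycle list turned to 0.21 without arrays of low quality. Within 3 plates the plasma cell difference was 0.51 to 0.75, below its mean of 1.16 over all lines, the secretory difference was 0.52 to 1.41 and the B cell difference -2.77 to -2.08. The MHC class II difference changed sign between these plates, from -3.22 to 0.30.

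**Figure D1:**
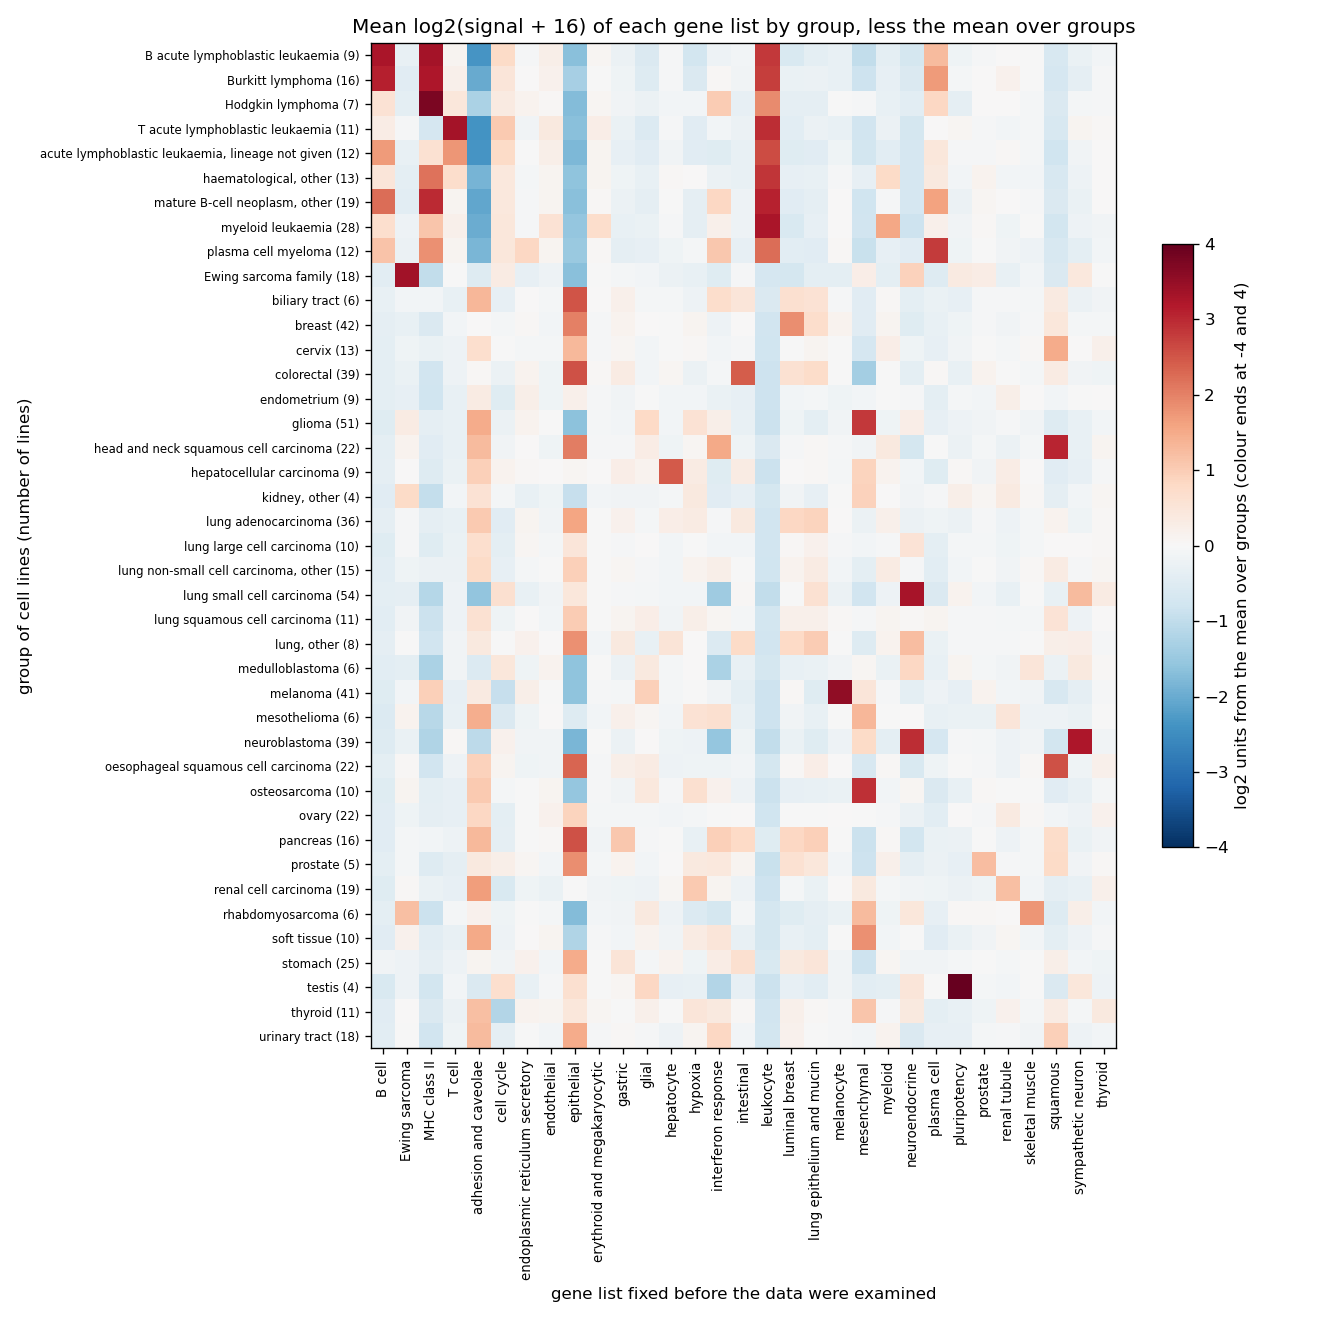
Mean log2(signal + 16) over the measured genes of each gene list (columns), averaged over the lines of each group of at least 4 lines (rows, number of lines in parentheses) and given as the difference from the mean over groups. Colour is red above and blue below that mean, in log2 units, with the colour scale ending at -4 and 4. The pluripotency list stood highest in the 4 testis lines, the melanocyte list in the 41 melanoma lines and the sympathetic neuron list in the 39 neuroblastoma lines.

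The 8 comparisons that follow set the lines of 1 solid group against the mean of 28 other solid groups, each group weighted equally, to ask which genes mark a tissue of origin. In melanoma (41 lines against 553) 19 of 20 melanocyte genes were higher (camera adjusted p = 1.33e-90), with a mean difference of 3.79. SOX10 (6.45 ± 0.15), a neural crest transcription factor, was furthest up, at a mean of 11.21 ± 1.61 (SD) against 5.48 in breast lines, the next group. The pigment enzyme TYR (5.93 ± 0.18), the melanosome proteins PMEL (5.13 ± 0.21) and MLANA (4.63 ± 0.17), the calcium-binding S100B (5.76 ± 0.15) and the endothelin receptor EDNRB (5.33 ± 0.20) rose as well. TYR was called present on 78.0% of melanoma and 0.9% of the other lines. Of 19 glial genes 8 were higher and 1 lower (camera adjusted p = 3.68e-07), with the proteoglycan CSPG4 (3.04 ± 0.14) and the fatty acid binding protein FABP7 (2.91 ± 0.23), and S100B belonged to both lists. Of 23 epithelial genes 21 were lower (camera adjusted p = 5.00e-17), among them the protease inhibitor SPINT2 (-3.68 ± 0.28) and EPCAM (-3.70 ± 0.35), which was present on no melanoma line and at least 10.2-fold lower. The urea cycle enzyme ASS1 (-3.75 ± 0.34) and the neuronal hydrolase UCHL1 (-3.24 ± 0.39) also fell. Of 22 mesenchymal genes 6 rose and 4 fell (camera adjusted p = 0.242, median -0.28 and mean 0.28), with SPARC (3.71 ± 0.34) and VIM (3.10 ± 0.39) higher. Of 25 cell cycle genes 4 were lower (camera adjusted p = 3.68e-07, adjusted p = 0.245 with an estimated correlation), among them MKI67 (-1.39 ± 0.19) and TOP2A (-1.42 ± 0.19). Neuroendocrine genes fell in 4 of 20 (camera adjusted p = 0.0604), and leukocyte genes rose in 1 of 23 and fell in 3 (camera adjusted p = 0.619). In total 859 of 10458 genes passed, 491 higher and 368 lower. The count was 467 with an offset of 64 and 1412 with an offset of 1. With the mean of each gene's probe sets the median of the glial list turned to -0.021, and with a filter at 25% of the lines that list lost its call (adjusted p = 0.0796) although its median rose from 0.21 to 0.75. The melanocyte difference was 1.65 to 4.66 within 9 plates.

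In glioma (51 lines against 543) 20 of 22 mesenchymal genes were higher (camera adjusted p = 9.93e-39). COL1A2 (5.68 ± 0.34), a collagen I chain, had the largest difference, followed by the collagen VI chain COL6A3 (4.41 ± 0.27) and SPARC (4.18 ± 0.31), a matrix protein. COL1A2 reached a mean of 12.01 ± 2.91 (SD) in glioma and 12.34 in osteosarcoma, the highest other group. The matrix enzymes LOXL1 (3.55 ± 0.23) and MMP2 (3.44 ± 0.23), the growth factor PTN (3.99 ± 0.24) and the surface glycoprotein THY1 (3.46 ± 0.21) were also among the 10 largest rises. Of 19 glial genes 6 were higher and none lower (camera adjusted p = 2.45e-04), with the matrix protein tenascin C, TNC (2.74 ± 0.25), the secreted glycoprotein CHI3L1 (2.31 ± 0.25) and the intermediate filament NES (1.53 ± 0.25). Epithelial genes were lower for 22 of 23 (camera adjusted p = 2.87e-25), with EPCAM (-3.64 ± 0.32) and KRT19 (-3.64 ± 0.36), and the focal adhesion protein TES (-3.34 ± 0.21) fell outside that list. Of 17 hypoxia genes 4 were higher and 1 lower (camera adjusted p = 0.00738, adjusted p = 0.158 with an estimated correlation), with LOX (2.85 ± 0.26), which cross-links collagen and also belonged to the mesenchymal list, and the lipid droplet protein PLIN2 (-1.33 ± 0.28) lower. Sympathetic neuron genes fell in 3 of 27 (camera adjusted p = 0.0201, adjusted p = 0.383 with an estimated correlation), among them ISL1 (-1.37 ± 0.22). Melanocyte genes rose in 1 of 20 and fell in 1, ERBB3 (-2.22 ± 0.22) (camera adjusted p = 0.368), leukocyte genes rose in 1 of 20 and fell in 2 (camera adjusted p = 0.322), and none of 25 cell cycle genes passed (3 at an unadjusted p under 0.05, camera adjusted p = 0.794). In total 659 of 10266 genes passed, 437 higher and 222 lower, with 319 at an offset of 64 and 1104 at an offset of 1. The hypoxia list, with a median of 0.31, lost its call in batch 2 alone at 0.22 (adjusted p = 0.157), and the sympathetic neuron list, with -0.27, without arrays of low quality at -0.21 (0.0796). The mesenchymal difference was 1.68 to 3.90 within 7 plates and the glial one 0.26 to 1.22.

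In neuroblastoma (39 lines against 555) 26 of 28 sympathetic neuron genes were higher (camera adjusted p = 3.76e-63), by a mean of 3.29. The neuronal RNA-binding protein ELAVL4 (5.38 ± 0.19), the nicotinic receptor subunit CHRNA3 (5.32 ± 0.16), the oncogene MYCN (5.03 ± 0.23) and the microtubule regulator STMN2 (4.79 ± 0.23) were among them. HAND2-AS1 (5.73 ± 0.11), a transcript opposite the HAND2 gene, averaged 10.18 ± 1.93 (SD) against 5.04 in the next group, the Ewing sarcoma family. MAB21L2 (5.83 ± 0.18) and SOX11 (5.06 ± 0.26), developmental regulators, were also among the 10 largest rises. Neuroendocrine genes were higher in 17 of 20 (camera adjusted p = 1.71e-22), with CHGA (4.71 ± 0.25) and ISL1 (4.18 ± 0.25). Both lists share genes, ELAVL4, STMN2, CHGA and ISL1 among them. Of 20 interferon response genes 17 were lower (camera adjusted p = 1.77e-08, adjusted p = 0.110 with an estimated correlation), with ISG15 (-2.78 ± 0.32) and IFITM1 (-3.00 ± 0.35), and HLA-C (-4.22 ± 0.25), an MHC class I gene, was also lower. Of 10 MHC class II genes 3 fell (camera adjusted p = 0.0208, adjusted p = 0.420 with an estimated correlation), with HLA-DMA (-1.31 ± 0.21). Adhesion and caveolae genes fell in 15 of 23 (camera adjusted p = 4.95e-13), with CAV1 (-3.99 ± 0.33) and CAV2 (-3.73 ± 0.31), and S100A10 (-4.51 ± 0.28) and MYOF (-4.35 ± 0.27) had the largest falls of all. On the epithelial list 22 of 23 genes were lower (camera adjusted p = 6.87e-15), with DSP (-4.04 ± 0.31) and KRT18 (-4.08 ± 0.32). Among 22 mesenchymal genes 9 were higher and 1 lower (camera adjusted p = 0.0315, adjusted p = 0.421 with an estimated correlation), with TWIST1 (3.08 ± 0.25) and CDH2 (2.55 ± 0.32), N-cadherin. Of 19 glial genes 3 were higher and 2 lower (camera adjusted p = 0.912, median -0.15 and mean -0.10), and none of 25 cell cycle genes passed (20 at an unadjusted p under 0.05, camera adjusted p = 0.0218, adjusted p = 0.559 with an estimated correlation). In total 1349 of 10501 genes passed, 583 higher and 766 lower, with 731 at an offset of 64 and 2035 at an offset of 1. The mesenchymal list, with a median of 0.20, lost its call with an offset of 64 at 0.097 (adjusted p = 0.0566) and with plate as a block at 0.18 (0.0645), and the cell cycle list, with 0.44, in batch 2 alone at 0.29 (0.205). The sympathetic neuron difference was 2.56 to 4.61 within 8 plates and the interferon one -2.26 to -1.05.

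In the Ewing sarcoma family (18 lines against 576) 17 of 19 genes of the Ewing sarcoma list were higher (camera adjusted p = 3.94e-49). The homeobox transcription factor NKX2-2 (6.09 ± 0.31), a target of the fusion protein of this tumour, the kinase PRKCB (5.55 ± 0.22), BCL11B (5.41 ± 0.25) and the peptide hormone CCK (4.98 ± 0.23) were among the 10 largest rises. ITM2A (6.66 ± 0.27) had the largest rise, at a mean of 11.47 ± 1.05 (SD) against 7.37 in rhabdomyosarcoma, and NCKAP1L (5.16 ± 0.12), an actin regulator of blood cells, was present on all lines of the group and 0.9% of the others. GAS1 (5.27 ± 0.38), a hedgehog coreceptor, and SOX11 (5.01 ± 0.37) rose as well. Of 20 neuroendocrine genes 6 were higher and 1 lower (camera adjusted p = 0.0390, adjusted p = 0.578 with an estimated correlation), with the gastrin-releasing peptide GRP (4.43 ± 0.35) and SYT1 (2.74 ± 0.40). Sympathetic neuron genes rose in 5 of 28 (camera adjusted p = 0.118), with NPY (2.14 ± 0.30). Lower levels marked 21 of 23 epithelial genes (camera adjusted p = 7.28e-12, adjusted p = 0.0933 with an estimated correlation), among them KRT8 (-3.65 ± 0.41) and KRT19 (-3.87 ± 0.58), present on no line of the group and at least 12.3-fold lower. The galectin LGALS3 (-5.55 ± 0.43), the calcium-binding S100A6 (-4.97 ± 0.48) and MYOF (-4.88 ± 0.39) had the largest falls. Mesenchymal genes rose in 6 of 22 and fell in 7 (camera adjusted p = 0.745), with ZEB2 (2.13 ± 0.17) higher and CDH2 (-2.62 ± 0.46) lower. Of 25 cell cycle genes 2 were higher (camera adjusted p = 0.00522, adjusted p = 0.578 with an estimated correlation), RRM2 (1.10 ± 0.32) and CDK1 (1.02 ± 0.23). Of 26 leukocyte genes 3 were higher and 1 lower (camera adjusted p = 0.745), with VAV1 (1.44 ± 0.19) and ITGB2 (1.26 ± 0.25) up. In total 1397 of 11060 genes passed, 602 higher and 795 lower. The count was 768 with an offset of 64, 2133 with an offset of 1 and 304 in batch 2 alone. The neuroendocrine list, with a median of 0.40, lost its call with an offset of 64 at 0.13 (adjusted p = 0.125), the mean of probe sets at 0.28 (0.0628), all other solid lines pooled at 0.24 (0.254), and a filter at 25% of the lines, where its median rose to 0.80 (0.0636). The ACTB ratio of RNA degradation was 1.94 ± 1.21 (SD) in the Ewing lines and 2.77 ± 1.65 in the others. Both plates with at least 2 lines of the group gave list differences of 3.37 and 3.42.

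In colorectal lines (39 against 555) 16 of 17 intestinal genes were higher (camera adjusted p = 7.03e-47). TSPAN8 (5.11 ± 0.36), CDH17 (4.71 ± 0.24), LGALS4 (3.99 ± 0.21) and KRT20 (3.48 ± 0.20) had the largest differences of the list, and CDH17 averaged 9.52 ± 3.11 (SD) against 7.39 in lung lines outside the main carcinoma types. The Wnt antagonist RNF43 (3.57 ± 0.18), the microvillus protein VIL1 (3.44 ± 0.20) and the growth factor BMP4 (3.37 ± 0.26) were also among the 10 largest rises. Of 23 epithelial genes 22 were higher (camera adjusted p = 2.91e-25), with EPCAM (3.60 ± 0.36) and the tight junction gene CLDN7 (2.94 ± 0.28). Of 22 mesenchymal genes 17 were lower and 1 higher (camera adjusted p = 1.16e-14), with VIM (adjusted p = 1.86e-19), CDH2 (-3.31 ± 0.32) and FN1 (-3.34 ± 0.43). BASP1 (-4.13 ± 0.39), TUSC3 (-3.58 ± 0.26) and UCHL1 (-3.46 ± 0.40) fell outside that list. Of 9 gastric genes 3 were higher (camera adjusted p = 0.224), the transcription factor GATA6 (1.38 ± 0.21) and the trefoil peptides TFF1 (1.13 ± 0.30) and TFF2 (1.03 ± 0.16). None of 17 hepatocyte genes (2 at an unadjusted p under 0.05, camera adjusted p = 0.937, with a mean of 0.01) and none of 25 cell cycle genes passed (4 at an unadjusted p under 0.05, camera adjusted p = 0.800). In total 765 of 10501 genes passed, 377 higher and 388 lower, with 370 at an offset of 64 and 1283 at an offset of 1. The intestinal difference was 1.81 to 3.53 within 8 plates and the epithelial one 0.11 to 3.28.

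In breast lines (42 against 552) 18 of 20 luminal breast genes were higher (camera adjusted p = 3.98e-46), by a mean of 1.84. The transcription factors GATA3 (3.04 ± 0.30) and SPDEF (2.37 ± 0.16), the secreted glycoprotein AZGP1 (3.16 ± 0.27) and the zinc finger protein TRPS1 (2.31 ± 0.21) were among them. GATA3 averaged 9.96 ± 2.81 (SD), below the 11.29 of neuroblastoma. EFHD1 (3.71 ± 0.27), a mitochondrial calcium-binding protein, and MGP (3.53 ± 0.31), matrix Gla protein, had the largest rises of all genes, and the transcription factor TFAP2C (2.81 ± 0.29) rose too. Higher levels marked 21 of 23 epithelial genes (camera adjusted p = 1.65e-25), with KRT19 (2.53 ± 0.39) and the small GTPase RAB25 (2.42 ± 0.30). Of 22 mesenchymal genes 7 were lower (camera adjusted p = 2.63e-06, adjusted p = 0.0623 with an estimated correlation), with ZEB1 (-1.87 ± 0.24), a repressor of E-cadherin, and VIM (-1.58 ± 0.39). The RNA-binding protein IGF2BP3 (-2.87 ± 0.24), the lactate dehydrogenase subunit LDHB (-2.42 ± 0.27) and HMGA2 (-2.32 ± 0.33) fell as well. Of 22 squamous genes 2 were higher, KRT15 (1.14 ± 0.27) and SFN (1.02 ± 0.28) (camera adjusted p = 0.114). None of 25 cell cycle genes (2 at an unadjusted p under 0.05, camera adjusted p = 0.133) and none of 20 interferon response genes passed (4 at an unadjusted p under 0.05, camera adjusted p = 0.152). In total 322 of 10458 genes passed, 182 higher and 140 lower. The count was 145 with an offset of 64, 671 with an offset of 1 and 9 in batch 2 alone, where KRT15 and FXYD3 and the medians of the squamous and mesenchymal lists changed sign. The luminal difference was -0.04 to 3.12 within 8 plates and the epithelial one -0.58 to 3.06.

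In hepatocellular carcinoma (9 lines against 585) 20 of 23 hepatocyte genes were higher (camera adjusted p = 2.41e-119), by a mean of 2.57. Among them were genes of proteins that liver secretes into blood: transferrin, TF (4.04 ± 0.42), the fibrinogen chain FGG (3.78 ± 0.40), angiotensinogen, AGT (3.76 ± 0.47), and the apolipoprotein APOB (3.74 ± 0.25). The spread was wide, since APOB averaged 8.23 ± 4.46 (SD) and was called present on 44.4% of the 9 lines against 0.7% of the others. The hepatocyte score of the 9 lines had a median of 5.17 and a highest value of 11.45. The standard errors and p-values, pooled over all groups, do not reflect this spread among the hepatocellular lines. SELENOP (4.07 ± 0.66), a selenium carrier, the aldehyde dehydrogenase ALDH1A1 (3.76 ± 0.72) and the myosin light chain MYL9 (3.62 ± 0.66) were also among the 10 largest rises. Of 19 intestinal genes 2 were higher, the fatty acid binding protein FABP1 (2.55 ± 0.33) and VIL1 (1.67 ± 0.40) (camera adjusted p = 0.0683). Of 23 epithelial genes KRT8 (2.16 ± 0.57) was higher and SPINT2 (-1.85 ± 0.58) lower, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0545). Of 22 mesenchymal genes 3 were higher, 5 adjusted over the list alone (camera adjusted p = 0.0253, adjusted p = 0.506 with an estimated correlation), with COL1A2 (3.15 ± 0.77) and CDH2 (2.55 ± 0.65). Of 12 renal tubule genes 1 was higher, GGT1 (1.17 ± 0.34) (camera adjusted p = 0.0547), and none of 25 cell cycle genes passed (3 at an unadjusted p under 0.05, camera adjusted p = 0.0142, adjusted p = 0.506 with an estimated correlation). The potassium channel KCNK1 (-2.67 ± 0.56) and the protease BACE2 (-2.57 ± 0.52) were lower. In total 253 of 11367 genes passed, 207 higher and 46 lower. The count was 147 with an offset of 64, 157 with a filter at 25% of the lines and 42 without arrays of low quality, where SELENOP and KCNK1 missed the threshold (adjusted p = 0.111 and 0.108). The ACTB ratio of RNA degradation was 3.52 ± 1.61 (SD) in hepatocellular lines and 2.73 ± 1.64 in the others. The hepatocyte difference was 2.62 to 3.50 within 3 plates.

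In renal cell carcinoma (19 lines against 575) 7 of 12 renal tubule genes were higher (camera adjusted p = 1.34e-16). The kidney transcription factor PAX8 (2.98 ± 0.21), the sodium pump modulator FXYD2 (3.04 ± 0.22), the cadherin CDH16 (1.92 ± 0.16) and the transferase GGT1 (2.14 ± 0.24) were among them, and PAX8 averaged 9.85 ± 1.08 (SD) against 9.36 in ovary lines. Hypoxia genes were higher in 8 of 17 (camera adjusted p = 3.66e-08), with the carbonic anhydrase CA12 (3.18 ± 0.46), the lipid droplet protein PLIN2 (2.67 ± 0.44) and adrenomedullin, ADM (1.60 ± 0.42). SPP1 (5.97 ± 0.53), which encodes osteopontin, had the largest rise, and HAVCR1 (3.88 ± 0.17), a tubular injury marker, the potassium channel KCNJ16 (3.97 ± 0.23) and the adhesion molecule VCAM1 (3.86 ± 0.35) were also higher. The mesenchymal list of 22 genes had 5 higher and 1 lower (camera adjusted p = 0.286, median -0.37 and mean 0.19), with VIM (3.21 ± 0.56) and CDH2 (2.88 ± 0.45). The 23 epithelial genes had 3 higher and 6 lower (camera adjusted p = 0.186). The lower ones included CLDN7 (-1.92 ± 0.39), ESRP1 (-2.07 ± 0.42) and RAB25 (-2.15 ± 0.44), which were present on no renal line and at least 3.32-fold, 2.97-fold and 3.18-fold lower. TIMP3 (-2.53 ± 0.50), an inhibitor of matrix proteases, was at least 4.15-fold lower. None of 21 hepatocyte genes (4 at an unadjusted p under 0.05, camera adjusted p = 0.372, median -0.09 and mean 0.09) and none of 25 cell cycle genes passed (11 at an unadjusted p under 0.05, camera adjusted p = 0.0124, adjusted p = 0.694 with an estimated correlation). In total 642 of 11007 genes passed, 481 higher and 161 lower, with 314 at an offset of 64 and 1108 (683 higher and 425 lower) at an offset of 1. The median of the mesenchymal list was above 0 in batch 2 alone, and the cell cycle list, with a median of -0.43, lost its call with plate as a block at -0.24 (adjusted p = 0.132) and in batch 1 alone at -0.32 (0.0683). The ACTB ratio of RNA degradation was 1.85 ± 1.63 (SD) in renal lines and 2.78 ± 1.64 in the others. The renal tubule difference was 0.74 to 2.42 within 4 plates and the hypoxia one 0.54 to 1.47.

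**Figure D2:**
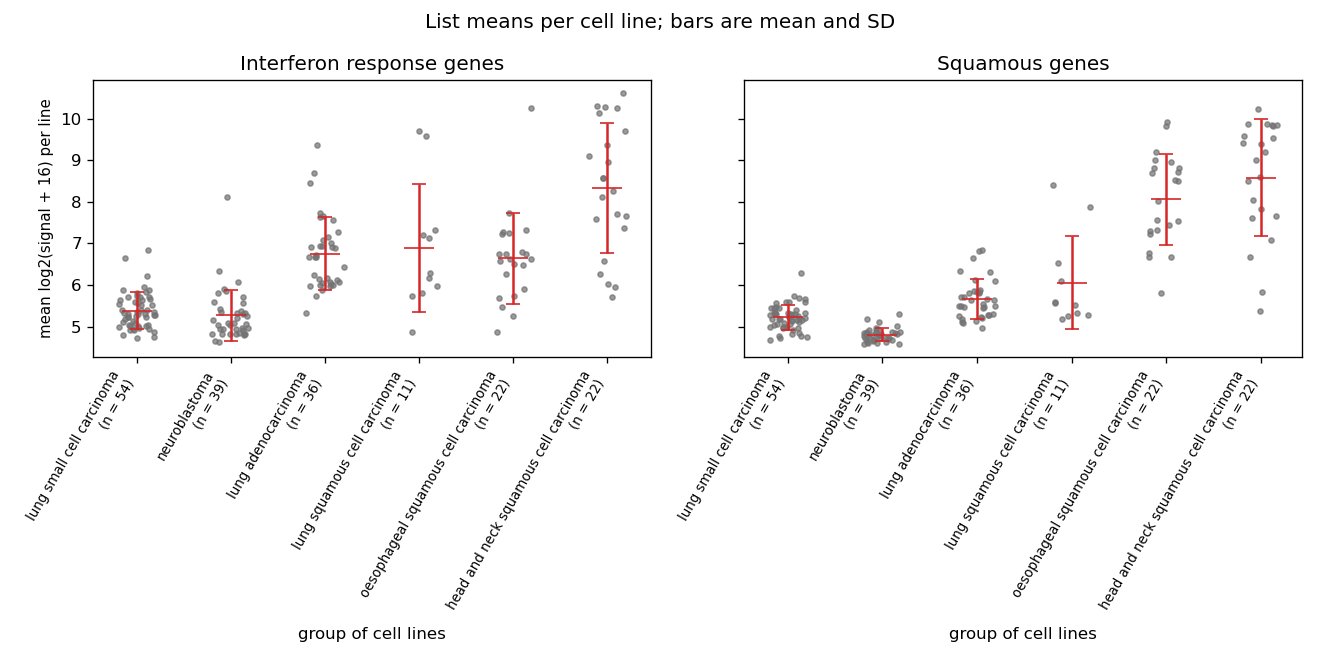
Mean log2(signal + 16) per cell line over the interferon response genes (left) and the squamous genes (right) in 6 groups, with the number of lines under each group name. Grey points are cell lines and red bars the mean and 1 SD. For squamous genes the mean was 6.06 in lung squamous lines, 8.59 in head and neck squamous lines and 5.67 in lung adenocarcinoma lines, with medians of 5.58, 9.11 and 5.59.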

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

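The tests of other splits of the lines between tumour groups were chosen after the results were seen, and those of the batch pairs before. In 100 splits of the lines into groups of the same sizes, the real one included, only the real one reached its count of passing genes in every comparison of tumour groups but that of lung squamous with adenocarcinoma lines. For a solid group against the others, the splits mixed the lines of all groups of the fit at once. They thereby removed every difference between tissues, so they do not test the named group alone. The counts lay above those of random groups, which does not tell their cause. These splits ignored plate, with which as a block the counts of oesophageal, T lymphoblastic and myeloma lines fell from 103 to 10, from 377 to 235 and from 455 to 171. The real count and the highest of the other splits were 1365 and 0 for haematological against solid lines, 1505 and 0 for small cell against other lung lines, 103 and 1 for oesophageal against head and neck squamous lines, and 172 and 1 for colorectal against stomach lines. They were 524 and 0 for myeloid against lymphoblastic leukaemia, 377 and 11 for T against B lymphoblastic leukaemia, and 455 and 3 for myeloma against mature B-cell lines. Against the other solid groups they were 859 and 0 for melanoma, 659 and 21 for glioma, 1349 and 1 for neuroblastoma, 1397 and 12 for the Ewing sarcoma family, 765 and 22 for colorectal, 322 and 5 for breast, 253 and 124 for hepatocellular and 642 and 38 for renal lines. For lung squamous against adenocarcinoma lines 3 of 100 splits, the real one included, gave at least 2 genes, and 1 of these 3 gave 5. With the signs of the 31 batch differences flipped, 1 of 100 gave as many as the real 1304 genes of any size, the highest other giving 1. For genes past both thresholds the flips decide nothing, since a real count of 0 (highest other 0) is met by 100 of 100 whatever the data.

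In groups of 4 to 10 lines, 13 of 84 sets of values had 1 line far from the rest, where chance picks out about 5 in 100 sets, or 4.2 of the 84. The sets share lines and genes, as the cell cycle score does with AURKA, CDC20 and RRM2, so they are not independent. The 13 against 4.2 therefore shows no excess by itself. The measure is the gap of the end line to its neighbour as a share of the whole range. In Hodgkin lymphoma lines it was 0.651 for the B cell score and 0.640 for the T cell score. In B lymphoblastic leukaemia lines it was 0.565 for the cell cycle score, 0.662 for AURKA, 0.706 for CDC20, 0.645 for RRM2, 0.616 for CD3G, 0.663 for CTSG and 0.534 for SH2D1A. In hepatocellular lines it was 0.505 for BACE2, 0.565 for CDH16, 0.617 for EPHB3 and 0.665 for SLPI. CD3G and SH2D1A were called present on no B lineage line, and EPHB3 on no hepatocellular line, so their values there are background signal. No explanation was tested for the 13 sets.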

How the results depend on the processing

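Batch 2 alone, supplier as a block, the ACTB covariate and the removal of low-quality arrays were chosen after the data were seen. No paired analysis was possible because the replicate numbers follow the order of the records, apart from the repeated lines, which were paired. The series value table could give no other value, being equal to the signals used in all 798 arrays. No scaling moved the median of all genes by more than 0.1. Named genes were counted once per comparison, 634 entries in all, so a gene named in several comparisons entered more than once. None that passed in either fit changed direction with each array scaled to 1 median, at both offsets or with no filter. The same held with the mean of probe sets and with plate as a block. Sign changes of entries passing in neither fit were not counted. In these settings the entries that no longer passed numbered 3, 10 and 51 (offsets of 1 and 64), 9, 23 and 43. Of the lists, 8 of 115 lost their call with plate as a block. The first array of a repeated line changed no list call and no count by over 1.5 times. Batch 2 alone, batch 1 alone and the removal of arrays leave fewer lines. Plate, supplier and the ACTB ratio were tested as causes for the interferon genes of oesophageal lines, and plate and the ACTB ratio for myeloma, with the observations; causes of the other changes were not tested.

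With an offset of 64 the counts were 794 for haematological lines, 874 for small cell lung, 1 for lung squamous, 91 for colorectal against stomach, 279 for myeloid leukaemia, 280 for myeloma, 467 for melanoma, 319 for glioma, 731 for neuroblastoma, 768 for Ewing sarcoma, 370 for colorectal, 145 for breast, 147 for hepatocellular and 314 for renal lines. With an offset of 1 they were 1412 for melanoma, 1104 for glioma, 2035 for neuroblastoma, 2133 for Ewing sarcoma, 1283 for colorectal, 671 for breast, 1108 for renal lines and 11 for the batch pairs. The spread of repeat arrays was 0.209 and 0.528 at offsets of 64 and 1. Lung squamous lines had 1 gene with each array scaled to 1 median, 1 with plate as a block, and 0 with a filter at 25% of the lines, with the mean of probe sets and in batch 1 alone (limma, with 1003, 1052 and 748 genes at an unadjusted p under 0.05). The 25% filter gave 157 for hepatocellular lines, and counting every probe set gave 723 for myeloma and 1 for the batch pairs. Median scaling gave 316 higher and 165 lower for myeloma, against 252 and 203.

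With plate as a block 10 genes passed for oesophageal, 235 for T lymphoblastic and 171 for myeloma lines. Supplier as a block gave 35 for oesophageal lines, and the ACTB covariate 224 for myeloma. Batch 1 alone gave 63 for oesophageal lines and 105 for colorectal against stomach. Batch 2 alone gave 830 for small cell lung, 4 for oesophageal lines, 15 for colorectal against stomach, 152 for myeloid leukaemia, 4 for myeloma, 304 for Ewing sarcoma and 9 for breast. Without arrays of low quality the counts were 17 for lung squamous, 69 for T lymphoblastic, 96 for myeloma and 42 for hepatocellular lines.

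Some directions turned. In batch 2 alone these were, in small cell lung, CEACAM6 (1.41) and the epithelial median (0.20), in oesophageal lines FN1 (0.064) and the cell cycle median (-0.18), in colorectal against stomach HSPA1A (1.00) and the interferon median (0.19), and in breast FXYD3 (-0.30), KRT15 (-0.72) and the mesenchymal (0.063) and squamous (-0.33) medians. The renal mesenchymal median was 0.10 there. Plate as a block turned the cell cycle median of oesophageal lines (-0.040), the removal of arrays that of myeloma (0.21), and the mean of probe sets the glial median of melanoma (-0.021).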

Other observations

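The tests of the interferon pattern, and the count of lung squamous lines above every adenocarcinoma line, were chosen after the result was seen. The other tests of the lung squamous lines and those of myeloma were set before their own results were seen. The patterns they address, such as the myeloma genes lost with a covariate, had been seen by then. Small groups outside the comparisons were described by the mean of a list per line, with its SD. All 4 testis lines were above every other solid line on the pluripotency list (10.37 ± 0.63 against 5.26 ± 0.32 in 624 lines), with L1TD1 at a mean of 12.71, GDF3 at 11.68 and NANOG, a factor that keeps embryonic stem cells undifferentiated, at 11.97. Of 6 rhabdomyosarcoma lines 3 were above every other solid line on the skeletal muscle list (6.59 ± 2.01 against 4.78 ± 0.19), with ACTC1, an actin of heart and developing muscle, at 9.05 and the acetylcholine receptor subunit CHRNA1 at 7.90. Of 5 prostate lines 2 were above every other solid line on the prostate list (5.95 ± 1.72 against 4.68 ± 0.23), with KLK3, which encodes prostate-specific antigen, at 6.77 and HOXB13 at 6.20.

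The 11 thyroid lines averaged 5.48 ± 0.41 on the thyroid list against 5.10 ± 0.27, with PAX8 at 8.36 against 6.82. The 6 mesothelioma lines averaged 8.00 ± 1.01 on the mesenchymal and 6.26 ± 0.58 on the epithelial list, against 6.80 ± 1.44 and 7.26 ± 1.98, while their keratins KRT7 and KRT8 averaged 8.65 and 10.40 against 6.94 and 8.83. The 6 medulloblastoma lines averaged 5.59 ± 0.55 on the sympathetic neuron list and 5.94 ± 0.39 on the glial list, against 5.40 ± 1.02 and 5.67 ± 0.48, with MAB21L1 at 8.87 and the neurofilament NEFL at 9.04. The 7 Hodgkin lymphoma lines averaged 5.67 ± 1.22 on the B cell list against 6.63 ± 1.60 in 120 other haematological lines, and 5.47 ± 0.33 against 5.68 ± 1.27 on the T cell list, where 6 of the 7 lay above the median of the others, with GATA3 at 9.66 against 6.86.

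Lung squamous and adenocarcinoma lines differed in 2 genes. Too few lines for any call is argued against by draws of 11 head and neck squamous lines against the same 36 adenocarcinoma lines, which gave a median of 452 genes (293 to 669 over 20 draws). That contrast is between organs and larger, with squamous means of 8.59 and 5.67 against 6.06 in lung squamous lines. The draws therefore cannot say whether 11 lines suffice for a smaller difference within lung. An array unable to measure squamous genes is argued against by the 21 of 21 squamous genes that passed between head and neck squamous and lung adenocarcinoma lines. A wide spread of squamous genes among lung squamous lines stays open, since the ratio of their SD to that of head and neck lines was 0.793 but within chance (1.11 and 1.40, two-sided permutation p = 0.290), and the SD in adenocarcinoma lines was 0.48. On the squamous list 2 of the 11 lung squamous and 19 of the 22 head and neck lines lay above every adenocarcinoma line, so that most of these lung lines, not all, may keep less of the squamous programme, or carry histology labels that do not match it.

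Interferon genes were lower in oesophageal than in head and neck squamous lines by 1.69 ± 0.41 in the mean of the list per line. The difference was -1.61 ± 0.60 with plate, -1.88 ± 0.58 with supplier and -1.67 ± 0.40 with the ACTB ratio in the fit, so none of these may be its whole cause. Camera with an estimated correlation gave adjusted p = 0.0362 with no term and 0.146, 0.114 and 0.0491 with these terms, and 103, 10, 35 and 118 genes passed. The passing genes kept a median of 98.7% of their difference with plate, while their median standard error rose from 0.38 to 0.53. A biological difference between the tissues stays open and untested, and within 3 plates the difference ran from -3.12 to -0.01.

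Of the 455 genes called between myeloma and mature B-cell lines, 199 were kept with the ACTB ratio as a covariate and 148 with plate as a block. The genes kept a median of 87.3% of their difference with the ACTB ratio (quartiles 75.0% and 96.1%) and 86.3% with plate (quartiles 74.3% and 96.4%), with all 455 of the same sign. Their median size went from 1.47 to 1.33 and 1.31, and the median standard error from 0.39 to 0.40 and 0.41. With the ACTB ratio or plate, each in a fit of its own, most of the median difference over the 455 genes therefore stayed. A part of each difference may belong to these terms. The genes were chosen for their size in these same lines, so the shares and signs do not settle the cause gene by gene. Degradation that the ACTB ratio does not capture was not tested. The ratio differed by plate, so these fits do not separate RNA degradation from plate. Of the 455, 337 and 330 stayed at least 1 in size.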
